A study of Mus musculus with 9 samples.

How the data were processed

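Total RNA of pooled peripheral blood from mouse embryos was profiled on 9 Affymetrix whole-genome mouse expression arrays, 3 per genotype. Per the labels' protocols, RNA was extracted with RNA-STAT and labelled with biotin by the one-cycle method of the array's maker. The submitters' processing notes name Affymetrix Expression Console 1.0, RMA and Partek 6.5, without saying which step each did. The deposited values, in 1 table of 45101 probe sets by 9 arrays, run from 1.49 to 14.56 and were taken as log2, from this range and from RMA being named, since the labels do not state the scale. RMA, as a method, subtracts background, equalizes the distributions of the arrays and summarizes the probes of a set. In the deposited table the sorted columns lay within 0.099 of their mean, and array medians lay between 4.27 and 4.30. Any uniform difference in RNA content between genotypes is removed by such equalization. Scanner files and detection calls were not used here, so signal over background is unknown.

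The 64 control probe sets were kept out of the tests, which left 45037. GEO's platform annotation named 1 gene for 34945 of them and several for 932, and 9160 were not named in it. Symbols were checked through Entrez identifiers against RefSeq names of assembly GRCm38.p6, where 34741 matched and none changed. No gene was named from a probe set with several symbols, and no coordinates are given. At gene level, each of 18193 genes was represented by its probe set with the highest mean over the 9 arrays, and disagreement between probe sets is given for genes where it mattered.

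Genotype was taken from the sample titles. A linear model of genotype was fitted to the deposited log2 values of all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), so that the 3 groups share an estimate of the spread. The tests were 2-sided, adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. The gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. Lists of cell types, pathways and complexes, 29 in all, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 87 tests (29 lists in 3 contrasts). Camera with an estimated correlation was adjusted in the same way. Counts of list members use the adjustment over all probe sets. Adjusted over the list alone, 17 macrophage and 14 megakaryocyte genes were lower in homozygous than in wild-type blood, and 1 megakaryocyte gene was higher. Several lists share members.

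Genes named in the text follow a rule: per contrast, the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap, passing over predicted genes and clone names; Cbfb, Runx1 and Myh11 in every contrast; and from each list up to 4 called members with the largest change, or up to 2 uncalled ones as values. C1qb, Col1a1, the other probe sets of Csf1r, Kit, Xist, Lyve1 and Csf2rb, and probe sets shared by adult globin genes were added after their values were seen. To judge how far shared wild-type arrays make the mutant changes correlate, arrays without any effect were simulated 20 times, and so were arrays with the measured homozygous changes and no heterozygous change; the latter was added after the values were seen. Both take the noise of a probe set as independent between arrays and probe sets.

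The procedure was tested on simulated arrays with the real means and spreads, in which 200 of 45037 probe sets were changed in the homozygous group. In the homozygous against wild-type contrast it recovered 8.0% of changes of 0.25 on the log2 scale and 68.0% of changes of 0.5. Changes of 1 and 2 were recovered in 94.0% and 100%, and 8 of 44837 unchanged probe sets were called. The simulation used independent noise and changed far fewer probe sets than the 9019 called in this contrast of the real arrays. Its recovery rates and false calls therefore need not hold there.

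The alternatives were a fit of only the groups compared, the replicate number as a block, a filter on the 40% dimmest probe sets, a variance prior with an intensity trend, no variance moderation, array weights, cyclic loess and quantile normalization, scaling to reference genes or to the array median, tests at gene level in 2 ways, leaving out probe sets ending in _x_at or _s_at, a 2-fold minimum, a threshold of 0.01, leaving out each array, and for gene lists an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9. A list whose camera direction changes sign is counted as reversed only where it is called in at least 1 of the settings.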

Results

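Gene expression was measured in peripheral blood of mouse embryos at E12.5 that carried 0, 1 or 2 copies of a knock-in allele of Cbfb. Cbfb encodes the subunit of core binding factor that does not itself bind DNA, and its DNA-binding partners are the RUNX proteins. The fusion protein CBFβ-SMMHC joins CBFβ to smooth muscle myosin heavy chain, encoded by Myh11, and the series title concerns the C-terminus of this fusion protein. The allele ΔC95 is named in the labels without further description. Heterozygous parents gave wild-type (Cbfb+/+), heterozygous (Cbfb+/ΔC95) and homozygous (CbfbΔC95/ΔC95) embryos on a mixed C57BL6/129SvEv background. Blood of 8 to 10 embryos of a genotype was pooled, and 3 arrays were hybridized per genotype, 9 in all. The number of arrays limits the precision. The labels do not say whether the 3 arrays of a genotype came from separate pools, so the p-values measure the spread between these arrays, which may be technical.

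Arrays of the same genotype correlated at r = 0.996 to 0.998 across 45037 probe sets, and homozygous against wild-type arrays at 0.987 to 0.988. The first principal component held 56.2% of the variance and placed the heterozygous arrays between the other groups. Control probe sets also differed by genotype. The poly-A spike-ins, bacterial transcripts added to the RNA before labelling, had a mean log2 value of 10.38 ± 0.02 in wild-type, 11.26 ± 0.00 in heterozygous and 11.96 ± 0.02 in homozygous arrays (SD, n = 3 each, 24 probe sets). Hybridization spike-ins, added after labelling, were at 10.32 ± 0.01, 10.32 ± 0.04 and 10.60 ± 0.07 (SD, n = 3 each, 18 probe sets). Values are relative within an array. With the poly-A spike-in means set equal, homozygous changes from wild type would be lower by 1.58, and heterozygous changes by 0.88. The size depends on the spike-in. Single probe sets differed from wild type by 0.91 to 2.14 in homozygous and by 0.48 to 1.10 in heterozygous arrays. Some probe sets of sex-linked transcripts differed as well. Xist, transcribed from the inactive X chromosome, was at 8.89, 9.86 and 10.11 in wild-type, heterozygous and homozygous blood by its brightest probe set. Its other probe sets gave -0.28, and -0.24 that did not pass the test, in homozygous minus wild-type blood, so the direction for Xist in that contrast depends on the probe set. In heterozygous minus wild-type blood they gave 0.28, and 0.12 that did not pass, the direction of the brightest. The Y-linked Eif2s3y was at 6.12, 4.73 and 5.65 by its brighter probe set. The other 8 probe sets of Y-linked genes, 4 of Uty, 3 of Kdm5d and 1 of Eif2s3y, did not pass the test against wild type in either genotype, at wild-type means of 1.82 to 4.77. Among them, 1 Kdm5d probe set was higher in homozygous than in heterozygous blood, by 0.35 (adjusted p = 0.0462), the direction of Eif2s3y at 0.92. The 3' minus 5' log2 ratio, a measure of RNA integrity, was 1.20, 1.21 and 1.20 for Actb.

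**Figure D1:**
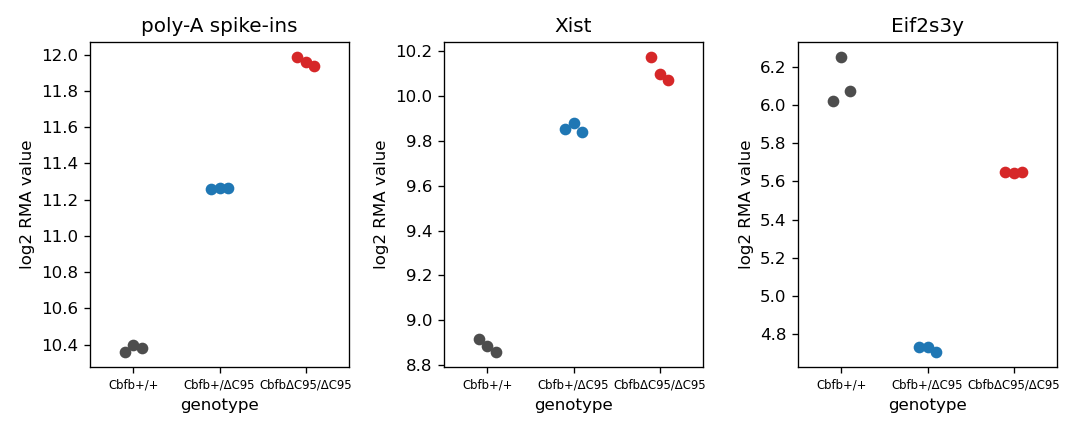
Mean log2 value of the poly-A spike-ins (left) and log2 RMA value of Xist (middle) and Eif2s3y (right), each point being 1 array, by genotype. The spike-ins step from 10.38 in wild-type to 11.26 in heterozygous and 11.96 in homozygous arrays, and the points of a genotype lie close together.

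The targeted gene was read by a single probe set. Cbfb was at 6.01 ± 0.03 in wild-type, 5.77 ± 0.04 in heterozygous and 5.10 ± 0.16 in homozygous blood (SD, n = 3). It was lower in homozygous than in wild-type blood by a log2 difference of -0.90 ± 0.08 (SE, adjusted p = 3.39e-06, limma). The heterozygous difference of -0.23 did not pass the test (adjusted p = 0.0928). Where this probe set lies relative to the altered part of the allele was not analysed here, so it does not check the labels. None of the 6 probe sets of Runx1 or the 2 of Myh11 passed the test in any contrast. By their brightest probe sets, the homozygous minus wild-type difference was 0.17 for Runx1 and 0.17 for Myh11. Of the 7 measured core binding factor genes and fusion partners, Runx1t1, a corepressor gene, was at -1.42 on the log2 scale and Runx3 at 0.29 in homozygous minus wild-type blood. The list did not pass (camera adjusted p = 0.611), and its mean of -0.23 and median of 0.17 differed in sign.

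The comparison of homozygous with wild-type blood asks what 2 copies of the allele change. Macrophage transcripts were among the largest falls. Csf1r, the receptor for macrophage colony-stimulating factor, changed by -3.48 ± 0.07 on the log2 scale (SE; 11.2-fold, adjusted p = 3.39e-11), and its other probe sets gave -1.46 and -0.78. The mannose receptor Mrc1 changed by -3.49, the Fc receptor Fcgr3 by -3.39, the lysozyme Lyz1 by -3.38, the adaptor Tyrobp by -3.21 and the complement component C1qc by -3.11. Of 21 measured monocyte and macrophage genes, 17 fell and 0 rose (mean log2 -1.88, camera adjusted p = 1.56e-19, and adjusted p = 0.00206 with an estimated correlation). The probe sets of C1qb disagreed in size, at -3.60, -2.79 and -0.73. Other genes among the largest falls were F13a1 at -3.56, Ms4a6b at -3.55, Selenop at -3.22 and the lysosomal protease gene Ctsc at -3.21.

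Megakaryocyte and platelet transcripts also fell, 14 of 19 measured, with none higher (mean log2 -0.90, camera adjusted p = 1.59e-08, and adjusted p = 0.0121 with an estimated correlation). The platelet chemokine genes Ppbp and Pf4 changed by -3.03 and -2.14 on the log2 scale, the platelet receptor subunit Gp1bb by -2.64, and Plek, a platelet signalling protein, by -1.71. Each of the 31 macrophage and megakaryocyte genes that fell was also called lower with cyclic loess, quantile normalization, array medians and reference genes. The homozygous arrays also differed from wild type in the spike-ins and in the brightest probe sets of Xist, at 1.22, and Eif2s3y, at -0.47, but not in Uty or Kdm5d by the test.

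**Figure D2:**
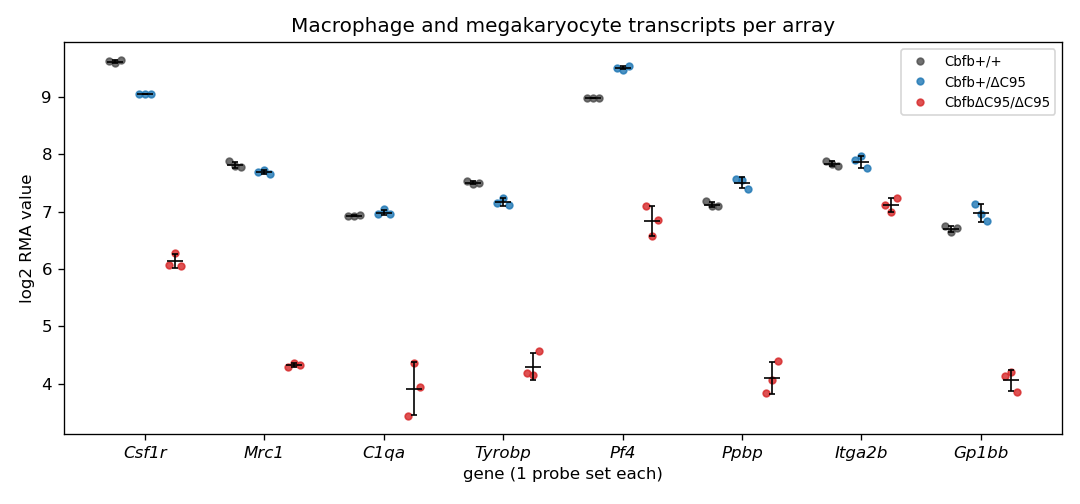
Log2 RMA values of 4 macrophage genes (Csf1r, Mrc1, C1qa, Tyrobp) and 4 megakaryocyte genes (Pf4, Ppbp, Itga2b, Gp1bb) in each array, with the mean and SD (black) of the 3 arrays per genotype. In homozygous arrays Csf1r averaged 6.14 against 9.62 in wild-type and 9.06 in heterozygous arrays, and Mrc1 4.33 against 7.82 and 7.69.

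Of the neutrophil and granulocyte genes, 4 of 17 fell, among them Mpo, which encodes myeloperoxidase, at -2.20. The list did not pass (camera adjusted p = 0.0997). Among reported RUNX1 target genes, 8 of 17 fell and 1 rose (camera adjusted p = 0.000814, but adjusted p = 0.0872 with an estimated correlation). Those that fell most were Csf1r, Mpo, Pf4 and the platelet integrin Itga2b, at -0.72, which other lists also hold. Of the stem and progenitor genes, 6 of 24 fell and 1 rose (camera adjusted p = 0.0959). Myb, a transcription factor of definitive progenitors, was at -1.98 and Cd34 at -0.83. Of 11 measured cytokine receptors of myeloid progenitors, Csf1r and Kit fell and Csf2rb2 rose by 0.60 (camera adjusted p = 0.502). Kit was read by a dim probe set, at 3.87 in wild-type and 3.56 in homozygous blood (adjusted p = 0.0183, limma). Its other probe set gave 0.10 and did not pass. The mast cell and basophil list held 1 lower gene of 13, Cpa3 at -1.22 (camera adjusted p = 0.77). The lymphoid list held 1 higher gene of 17, Rag2 at 0.23 (camera adjusted p = 0.353). The mean and median differed in sign for the cytokine receptors (-0.29 and 0.00), the mast cell list (-0.07 and 0.03) and the endothelium list (-0.02 and 0.01).

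Embryonic globin transcripts did not pass the test, singly or as a list (camera adjusted p = 0.66), with Hba-x at 14.30 in wild-type and 14.35 in homozygous blood. These values are near the top of the range of the arrays, which ends at 14.56, where a difference may not be readable. Some erythroid genes below that level changed, and others did not pass the test. Of 18 measured erythroid membrane and maturation genes, 11 fell and 2 rose (mean log2 -0.31, camera adjusted p = 9.74e-05, but adjusted p = 0.189 with an estimated correlation), with Trim10 at -1.11 and the glucose transporter Slc2a1 at -0.91. Of 16 heme synthesis and iron uptake genes, 8 fell and none rose (camera adjusted p = 0.00487, but adjusted p = 0.115 with an estimated correlation), led by the heme exporter Flvcr1 at -1.56. Of 17 erythroid transcription factors and Epo signalling genes, 9 fell and 3 rose (camera adjusted p = 0.00762, but adjusted p = 0.229 with an estimated correlation), with Klf3 at -1.24 and Tal1 at -0.96. Of 3 adult globin genes with a probe set of their own, Hba-a2 was at -0.78 (camera adjusted p of the list 0.116). Its probe set had a wild-type mean of 8.11. Brighter probe sets shared by several adult globin genes, at wild-type means of 13.41 to 14.50, gave -0.06 to 0.05 and did not pass.

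Genes of DNA replication and S phase rose in homozygous blood, 11 of 22 with none lower (mean log2 0.42, camera adjusted p = 1.59e-06, but adjusted p = 0.204 with an estimated correlation). The replication licensing genes Cdc6, Cdt1 and Mcm5 rose by 1.36, 1.21 and 1.21. Mitosis genes went the other way, with 12 of 21 lower and 1 higher (camera adjusted p = 0.00014, but adjusted p = 0.206 with an estimated correlation), for example Nusap1 at -0.94. Of 14 genes of cell cycle exit and CDK inhibitors, 9 fell and 1 rose (camera adjusted p = 9.74e-05, but adjusted p = 0.134 with an estimated correlation), with Gadd45a at -1.68 and the inhibitor Cdkn1b at -1.17. Glycolysis and hypoxia genes rose in 9 of 20 and fell in 2 (camera adjusted p = 0.00149, but adjusted p = 0.121 with an estimated correlation). The glycolytic enzyme genes Tpi1 and Aldoa rose by 1.36 and 0.85. Liver and visceral endoderm genes rose in 8 of 20 with none lower (camera adjusted p = 0.00566, but adjusted p = 0.0872 with an estimated correlation). Afp, which encodes alpha-fetoprotein, rose by 1.06 and Apoa1 by 0.82.

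Interferon response genes fell in 7 of 22 (camera adjusted p = 0.00173, but adjusted p = 0.0665 with an estimated correlation), with Rsad2 at -1.95. Immediate early genes fell in 7 of 19 and rose in 2 (camera adjusted p = 0.0389, but adjusted p = 0.279 with an estimated correlation), with Klf6 at -1.47 and Fos at -1.04. Of 20 genes of the unfolded protein and heat shock response, 9 fell and 4 rose (camera adjusted p = 0.0389, but adjusted p = 0.304 with an estimated correlation). Dnajb9 was at -1.21 and the mitochondrial chaperonin Hspe1 at 0.90. Mesenchyme and extracellular matrix genes fell in 8 of 18 and rose in 1 (camera adjusted p = 0.0389, but adjusted p = 0.141 with an estimated correlation), with Col3a1 at -0.94 and Fn1, the gene that rose, at 0.88. Lists that did not pass were apoptosis and p53 (7 lower and 2 higher of 17), ribosomal proteins (1 lower and 4 higher of 17), endothelium (1 lower of 19), neural (2 higher of 15), skeletal and cardiac muscle (1 lower and 2 higher of 14) and epithelium and placenta (2 higher of 9). The remaining genes among the 10 largest rises were Atp1b2 at 1.54, Itpka at 1.40, Alg3 at 1.31, Sgf29 at 1.25, Nme1 at 1.24 and Xist at 1.22. Adjusted over the list alone, the number of genes higher and lower was 14 and 0 for replication, 2 and 13 for mitosis, 10 and 3 for glycolysis, 4 and 11 for the unfolded protein response, 3 and 9 for immediate early genes, 0 and 17 for macrophage genes and 3 and 2 for core binding factor genes. For the other lists each number moved by at most 1.

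In total 9019 of 45037 probe sets differed between homozygous and wild-type blood (limma, adjusted p under 0.05), 3758 higher and 5261 lower. Of these, 48 were higher and 598 lower by at least 2-fold. At gene level, 4661 of 18193 genes differed. The arrays of the genotypes did not overlap in 7144 of the 18193 genes (39.3%), an arrangement that chance gives in 10%. Setting arrays to equal means of reference genes gave 5214 higher among 9950 called probe sets. Of the 29 gene lists, 3 shifted up and 12 down, and 2 calls, macrophage and megakaryocyte, held with an estimated correlation. The calls of mesenchyme, unfolded protein response and immediate early genes were lost without wild-type replicate 1 and under several other settings, and that of erythroid transcription factors with quantile normalization.

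**Figure D3:**
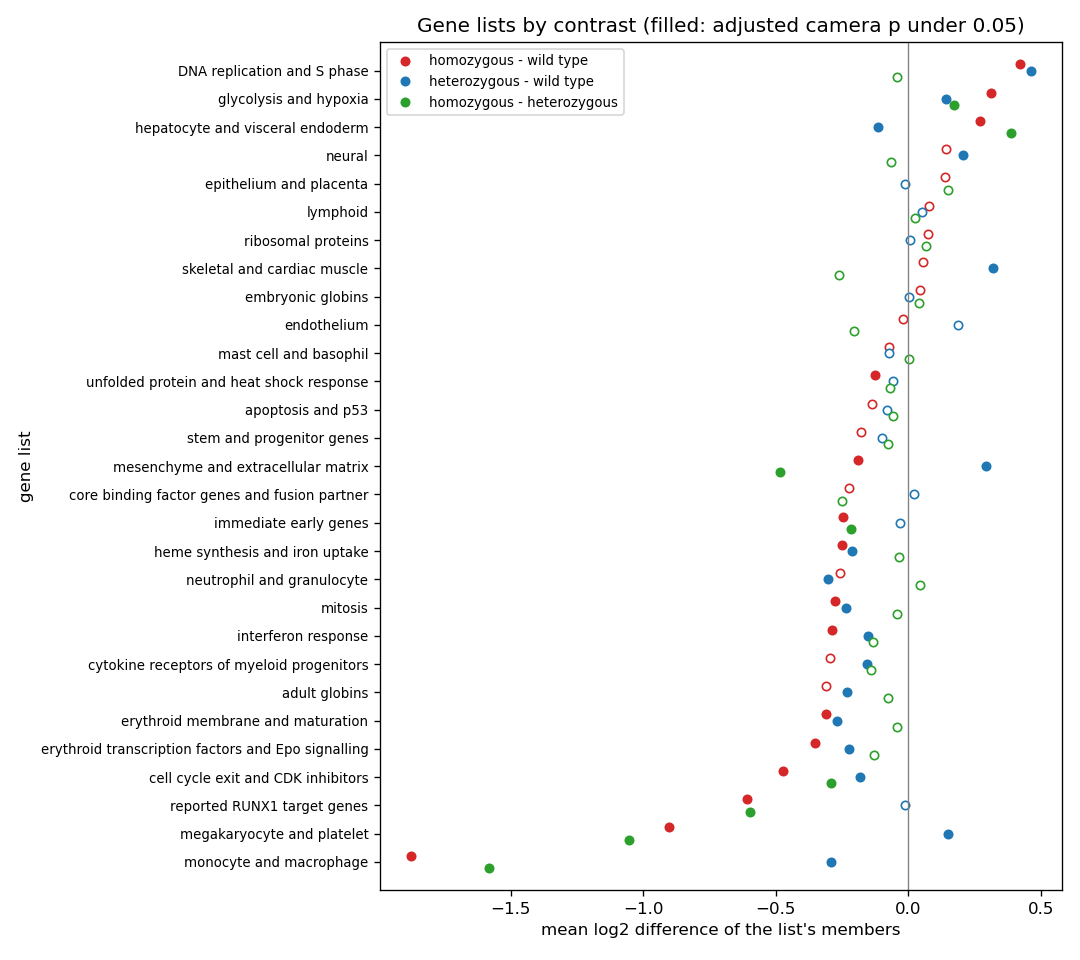
Mean log2 difference of the measured members of each of 29 gene lists in the 3 contrasts. Filled points passed camera with a preset correlation at an adjusted p under 0.05. The monocyte and macrophage list has the lowest mean in homozygous against wild-type blood, -1.88, and was at -0.29 in heterozygous against wild-type blood.

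The comparison of heterozygous with wild-type blood asks what 1 copy of the allele changes. The largest rise was in Lyve1, a hyaluronan receptor gene of endothelium and some macrophages, at 2.98 ± 0.07 on the log2 scale (SE; 7.89-fold, adjusted p = 2.76e-09). Its other probe set gave 0.29 and did not pass. The cardiac actin gene Actc1 was higher 5.65-fold, and the imprinted genes Nnat and Mest rose by 1.42 and 1.31. Mesenchyme and extracellular matrix genes rose in 7 of 18 and fell in 1 (mean log2 0.29, camera adjusted p = 9.35e-05, and adjusted p = 0.0362 with an estimated correlation), among them the collagen genes Col3a1 at 0.93 and Col1a2 at 0.53. Neural genes rose in 5 of 15 (camera adjusted p = 0.00221, but adjusted p = 0.0676 with an estimated correlation), with Tubb3 at 0.80. Skeletal and cardiac muscle genes rose in 4 of 14 (camera adjusted p = 0.00549, but adjusted p = 0.173 with an estimated correlation), with Myog at 0.62 after Actc1. Other genes among the 10 largest rises were Marcksl1 at 1.26, Crabp1 at 1.22, Tubb2b at 1.20 and Itpka at 1.18.

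**Figure D4:**
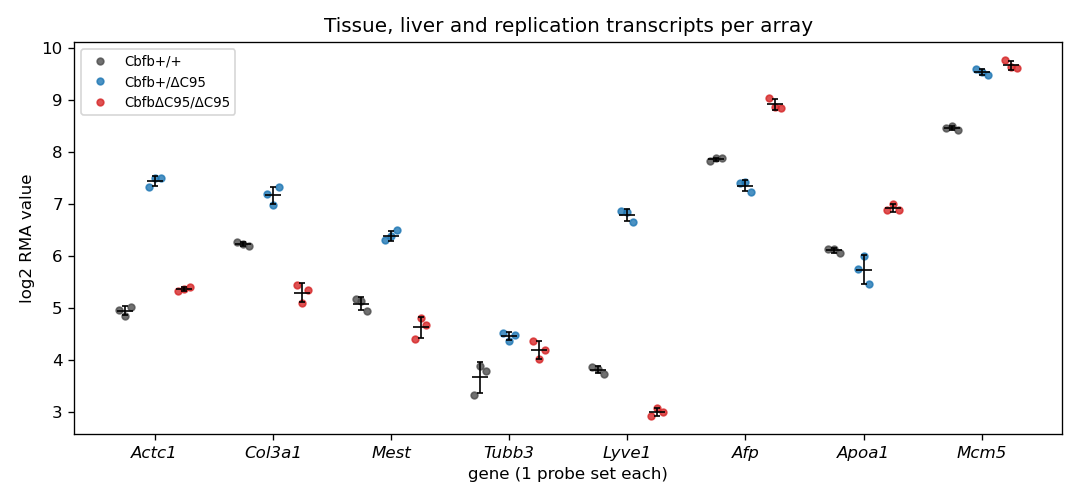
Log2 RMA values of Actc1, Col3a1, Mest, Tubb3, Lyve1, Afp, Apoa1 and Mcm5 in each array, with the mean and SD (black) of the 3 arrays per genotype. Heterozygous arrays averaged 7.44 for Actc1 against 4.95 in wild-type and 5.36 in homozygous arrays, while Mcm5 averaged 9.53, 8.46 and 9.67 in the same order.

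Monocyte and macrophage genes fell in 8 of 21 and rose in 1 in heterozygous blood (mean log2 -0.29, camera adjusted p = 1.2e-05, and adjusted p = 0.0248 with an estimated correlation). Lyz1 was at -1.36, Lyz2 at -1.15, the protease Ctss at -1.07 and Csf1r at -0.56. Megakaryocyte and platelet genes shifted up, with 2 of 19 higher and none lower (camera adjusted p = 0.00763, but adjusted p = 0.0921 with an estimated correlation), and Pf4 was at 0.52. Neutrophil and granulocyte genes fell in 5 of 17 (camera adjusted p = 0.000234, but adjusted p = 0.0519 with an estimated correlation), led by S100a8 at -1.32 and S100a9 at -0.94. The cytokine receptor list shifted down with 2 of 11 lower (camera adjusted p = 0.0295, but adjusted p = 0.134 with an estimated correlation). Among these was Csf2rb, the common beta chain of the receptors for several myeloid cytokines, at -0.68.

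Heme synthesis and iron uptake genes fell in 5 of 16 (camera adjusted p = 1.14e-05, and adjusted p = 0.0373 with an estimated correlation), with Flvcr1 at -0.69 and the transferrin receptor Tfrc at -0.49. Erythroid membrane and maturation genes fell in 9 of 18 and rose in 1 (camera adjusted p = 1.5e-07, but adjusted p = 0.115 with an estimated correlation). Erythroid transcription factors and Epo signalling genes fell in 8 of 17 and rose in 2 (camera adjusted p = 0.001, but adjusted p = 0.189 with an estimated correlation), with Myb at -1.21 and Lmo2 at -0.76. The adult globin list passed narrowly (camera adjusted p = 0.05 after rounding, but adjusted p = 0.189 with an estimated correlation), with 1 of 3 lower. The lower gene was Hba-a2, at -0.42. Brighter probe sets shared by several adult globin genes gave -0.02 to 0.03 and did not pass. Replication and S phase genes rose in 13 of 22 (mean log2 0.46, camera adjusted p = 2.83e-14, but adjusted p = 0.115 with an estimated correlation), with Cdt1 at 1.43, Cdc6 at 1.23 and Mcm5 at 1.07. Mitosis genes fell in 11 of 21 (camera adjusted p = 8.75e-07, but adjusted p = 0.159 with an estimated correlation). Genes of cell cycle exit fell in 5 of 14 and rose in 1 (camera adjusted p = 0.00207, but adjusted p = 0.189 with an estimated correlation), interferon response genes fell in 4 of 22 and rose in 1 (camera adjusted p = 0.00255, but adjusted p = 0.0676 with an estimated correlation), and glycolysis and hypoxia genes rose in 8 of 20 and fell in 2 (camera adjusted p = 0.00127, but adjusted p = 0.12 with an estimated correlation). The liver and visceral endoderm list shifted down (camera adjusted p = 0.0353, but adjusted p = 0.134 with an estimated correlation) with 1 of 20 lower, Afp at -0.51. The other genes among the 10 largest falls were Maob at -1.72, Plaat3 at -1.43, Nxpe2 at -1.41, Eif2s3y at -1.39 and Apoe at -1.27.

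In total 3855 probe sets differed between heterozygous and wild-type blood, 1536 higher and 2319 lower, with 35 higher and 24 lower by at least 2-fold. The number higher was 998 without heterozygous replicate 2 and 1017 without wild-type replicate 3. At gene level 2152 genes differed. Equal means of reference genes gave 6551 called probe sets, of which 745 were higher, since those reference genes lay higher by 0.11 in heterozygous than in wild-type arrays. Of the 29 lists, 6 shifted up and 11 down, and 3 calls, macrophage, mesenchyme and heme, held with an estimated correlation. Adjusted over the list alone, the number of genes higher and lower was 7 and 0 for megakaryocyte, 9 and 1 for mesenchyme, 7 and 0 for neural, 1 and 12 for erythroid membrane, 1 and 14 for mitosis, 0 and 4 for liver, 1 and 6 for interferon, 3 and 7 for unfolded protein and 5 and 4 for immediate early genes. For the other lists each number moved by at most 1. The other 12 lists did not pass, and the mean and median of the ribosomal protein and RUNX1 target lists, all near 0, differed in sign. The adult globin call was lost under most settings, the cytokine receptor call without wild-type replicate 2, heterozygous replicate 2 or homozygous replicate 1, and the liver call with reference genes or without wild-type replicate 3.

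Homozygous and heterozygous blood, which differ by 1 copy of the allele, were compared directly. Lyve1 differed by -3.79 in homozygous minus heterozygous blood, Ppbp by -3.41, Mrc1 by -3.36 and C1qa by -3.07. Monocyte and macrophage genes were lower in 17 of 21 (camera adjusted p = 5.85e-23, and adjusted p = 0.00206 with an estimated correlation) and megakaryocyte and platelet genes in 14 of 19 (camera adjusted p = 2.83e-14, and adjusted p = 0.00364 with an estimated correlation). Mesenchyme and extracellular matrix genes were lower in 9 of 18 and higher in 2 (camera adjusted p = 1.17e-05, and adjusted p = 0.0248 with an estimated correlation), with Col3a1 at -1.87 and Mest at -1.76. Liver and visceral endoderm genes were higher in 8 of 20 (camera adjusted p = 7.5e-06, and adjusted p = 0.0248 with an estimated correlation), with Afp at 1.56, Apoa1 at 1.19 and the retinol carrier Rbp4 at 1.19. Csf2rb was higher by 0.78 and Atf5 by 0.81. Reported RUNX1 target genes were lower in 8 of 17 (camera adjusted p = 0.000192, but adjusted p = 0.0676 with an estimated correlation), genes of cell cycle exit lower in 8 of 14 and higher in 1 (camera adjusted p = 0.00207, but adjusted p = 0.189 with an estimated correlation), immediate early genes lower in 7 of 19 and higher in 1 (camera adjusted p = 0.00482, but adjusted p = 0.189 with an estimated correlation), and glycolysis and hypoxia genes higher in 8 of 20 and lower in 1 (camera adjusted p = 0.00534, but adjusted p = 0.158 with an estimated correlation). The replication list did not pass in this contrast (camera adjusted p = 0.413).

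In total 5459 probe sets differed between homozygous and heterozygous blood, 1880 higher and 3579 lower, with 12 higher and 235 lower by at least 2-fold. The number higher was 1040 without heterozygous replicate 1 and 1084 without heterozygous replicate 2. At gene level 2867 genes differed. The balance of higher and lower also depended on the scaling: equal means of reference genes, which lay at -0.15 in homozygous minus heterozygous arrays, gave 20889 called probe sets, of which 18437 were higher. The F-test over the 3 genotypes called 8899 probe sets. Of the 29 lists, 2 shifted up and 6 down, and 4 calls, macrophage, megakaryocyte, mesenchyme and liver, held with an estimated correlation. Adjusted over the list alone, 17 macrophage and 14 megakaryocyte genes were lower and none higher. The number higher and lower became 3 and 8 for cell cycle exit, 3 and 4 for erythroid transcription factors, 3 and 2 for neutrophil, 4 and 0 for epithelium, 3 and 4 for apoptosis and 4 and 7 for unfolded protein genes, and moved by at most 1 for the other lists. The other 21 lists did not pass. Among these, the cytokine receptors had a mean of -0.14 and a median of 0.02.

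Changes from wild type in the mutant genotypes were then set against each other. Across probe sets, which are not independent replicates, the log2 changes correlated at r = 0.634, where arrays simulated without any effect but with the same controls gave 0.499. The covariance was 0.0306 against 0.00323 in the simulation, a difference of 0.0273. Of the called probe sets, 1038 were higher in both genotypes, where independent lists would share 128.2, and 2056 were lower in both, where independent lists would share 270.9. Part of the excess may come from the shared wild-type arrays, which were not split between the comparisons. Among the 9019 probe sets that differed in homozygous blood, 83.1% had a heterozygous value between the others, and the median ratio of heterozygous to homozygous change was 0.43. Arrays simulated with the homozygous changes, no heterozygous change, the same shared controls and the same selection gave 54.1% and 0.0155. For the 598 probe sets lower by at least 2-fold in homozygous blood it was 0.346, and for the 48 higher by at least 2-fold 0.594. For the list members that fell in homozygous blood it was 0.105 for 17 macrophage genes and -0.128 for 14 megakaryocyte genes. The poly-A spike-ins also stepped in the order of allele number, with a ratio of 0.558. Whether the intermediate heterozygous values follow allele number or a graded difference between preparations was not tested across all probe sets.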

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

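All tests of explanations in this part were chosen after the results they bear on were seen, except the counts of other splits of the arrays. Control transcripts outside the comparisons differed from the wild-type arrays: the poly-A spike-ins by 1.58 in homozygous and 0.88 in heterozygous arrays, and the hybridization spike-ins by 0.28 in homozygous arrays (log2). Single arrays were not tested as outliers in groups of 3.

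The spike-ins and the brightest probe sets of Xist and Eif2s3y stepped between genotypes with little spread within them, while the other Xist probe sets went the opposite way in homozygous blood (-0.28, and -0.24 that did not pass) and the other 8 Y-linked probe sets did not pass against wild type. For Actb and Gapdh, genotype means of the 3' minus 5' ratio differed by at most 0.0142, which argues against degradation by these measures. Other controls on the arrays, not in that test, were mixed. Homozygous minus wild-type differences at the 3' and 5' probe sets were 0.32 and 0.12 for pyruvate carboxylase. They were -0.03 and -0.03 for the transferrin receptor, and -0.20 and -0.10 for 18S RNA. A difference in integrity is therefore not excluded. Eif2s3y varied within genotypes by 0.070 (pooled SD), and 0.03% of 20000 simulated draws of independent pools of 8 to 10 embryos varied as little, under an assumed background and linear response to the share of males; this may come from the 3 arrays of a genotype sharing 1 pool, but it rests on 1 probe set that the other Y-linked ones, dim at wild-type means of 1.82 to 4.77, do not follow against wild type (1 of Kdm5d differed by 0.35 in homozygous minus heterozygous blood, adjusted p = 0.0462, the direction of Eif2s3y), a limit applied after the result was seen. If they did share a pool, the arrays would be technical replicates, and genotype could not be separated from pool in any comparison. A lower RNA input per mutant allele cannot be told apart from a difference between preparations, since each genotype has its own spike-in level: the heterozygous step was 0.558 of the homozygous one.

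Macrophage and megakaryocyte transcripts were lower in homozygous blood, with 31 of 40 measured genes called lower and 0 higher. A labelling effect on these genes that stepped like the spike-ins would give a heterozygous to homozygous ratio near 0.558. The median was 0.0317 over both lists (bootstrap 95% interval -0.104 to 0.105). It was 0.105 for macrophage genes (0.0317 to 0.288) and -0.128 for megakaryocyte genes (-0.243 to -0.00248). The genes were chosen by their homozygous fall, and the intervals resample genes of the same arrays, so they hold no variation between arrays or pools. A labelling difference common to all transcripts is removed by the equalization of arrays, so this ratio cannot test it. Under each of 4 other normalizations and scalings, 31 of the 31 genes stayed called lower. These settings moved the arrays little, with homozygous minus wild-type shifts of 0.02 for array medians and -0.04 for reference genes. The count therefore says little about larger differences in scaling. Scaling to the mean of the poly-A spike-ins, not among them, would deepen the falls by 1.58, or by 0.91 to 2.14 with single spike-in probe sets. Fewer macrophages and megakaryocytes in the pool may explain the falls, or lower expression per cell in this genotype, or a difference between pools. The last of these and expression per cell were not tested. As first formulated, a change in cell number alone would make bright members fall by a common amount. In the 4 lowered members with a wild-type mean of at least 8, the interquartile range of the changes, 1.91, was above the size of their median, -1.36. This goes against that formulation, but the members come from both lists, among them Csf1r and Pf4. Cell types lost to different degrees would also fall unequally, so the range cannot decide on cell number. The 4 genes were also judged, after seeing that result, too few to decide.

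In heterozygous blood 7 of 18 mesenchyme genes were higher and 1 lower, 5 of 15 neural and 4 of 14 muscle genes were higher (adjusted p = 0.0362, 0.0676 and 0.173 with an estimated correlation), the muscle list with a mean of 0.32 and a median of 0.05. A lower share of the main blood cells would raise other cell types alike, whereas the macrophage list moved by -0.29 with 8 genes lower and 1 higher. The neutrophil and liver lists also shifted down by camera with the preset correlation. By the same test, however, the megakaryocyte list shifted up and the erythroid lists down. These lists therefore go against a rise of all other cell types alike, but a lower erythroid share beside separate changes is not excluded. Embryonic tissue in the pool may also raise imprinted growth genes, a list chosen after the imprinted genes Nnat and Mest, which it leaves out, had been seen to rise: 6 of 19 measured members were higher and 2 lower than wild type (camera p = 0.0252, adjusted p = 0.0260, and p = 0.0510 with an estimated correlation, adjusted p = 0.0520). In homozygous blood 0 were higher and 5 lower than wild type (camera, adjusted p over the 3 contrasts = 0.0260, and adjusted p = 0.0520 with an estimated correlation), and 1 was higher and 8 lower than in heterozygous blood (adjusted p = 0.000133, and adjusted p = 0.0132 with an estimated correlation). The explanation stays open, since the list was chosen after the pattern was seen, the heterozygous p crosses the threshold with the correlation used, and Col1a1, an abundant mesenchymal transcript, was at 6.00 in wild-type and 6.02 in heterozygous blood; an effect of the genotype itself was not tested.

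Other splits of the arrays were counted for each comparison. For homozygous against wild-type arrays, the real split called 9019 probe sets (limma) and the highest of the other splits 0, and 1 of 10 splits gave as many; the counts were 3855 against 0 for heterozygous against wild type and 5459 against 0 for homozygous against heterozygous. For gene lists the real and highest other counts were 15 and 9, 17 and 8, and 8 and 7. With 10 splits no share under 0.05 is possible. For the F-test, 100 splits of the 9 arrays were drawn, the real one among them. Only the real split gave 8899 probe sets, and the highest other gave 3901. Arrays grouped by genotype therefore differed more than in the other drawn splits. Anything shared by the arrays of a genotype, such as a pool, would give this too, so the count cannot exclude it.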

How the results depend on the processing

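No alternative in this part was chosen after the data were seen. Of 277 named gene calls, 217 kept direction and side of the threshold under every alternative that left the threshold as it was. With the 2-fold minimum and the threshold of 0.01 counted too, 89 were kept. None reversed. The named genes were mostly picked for large changes in these same arrays, so the counts do not stand for the other calls. Of 40 list calls, 9 were kept under alternatives with the same threshold, and the other 31 were lost with an estimated correlation. Scaling to the poly-A spike-ins was not among the alternatives. By their mean it would lower homozygous changes from wild type by 1.58, heterozygous ones by 0.88, and homozygous minus heterozygous differences by 0.70. Called rises smaller than these shifts would then reverse. At the mean shift this holds for every gene named as higher in homozygous than in wild-type blood. It also holds for the means of the replication and liver lists in that contrast, 0.42 and 0.27. Counts of probe sets moved by over 1.5 times as follows, with the contrasts in the order homozygous against wild type, heterozygous against wild type, homozygous against heterozygous, and F-test. Scaling to reference genes gave 6551 for heterozygous against wild type, 20889 for homozygous against heterozygous and 19615 for the F-test. One probe set per gene gave 5128, 2482, 3302 and 5099, and the mean of probe sets per gene 5291, 2315, 3231 and 5187, since fewer features were tested. A 2-fold minimum gave 646, 59, 247 and 725. A threshold of 0.01 gave 2153, 3057 and 5905 for the last 3. The number of shifted lists was 2, 3 and 4 with an estimated correlation, and 25 and 22 with fry for homozygous against wild type and against heterozygous; fry does not compare a list with other genes. The list of cytokine receptors had a mean of -0.14 in homozygous against heterozygous blood, with fry's direction opposite to camera's uncalled one, as Csf1r fell far while the median was 0.02. Leaving out each array gave 7284 to 8846, 2665 to 4264, 3762 to 5166 and 7354 to 8605 probe sets, and 12 to 15, 15 to 17 and 8 to 9 lists. The number of probe sets higher was 2760 to 3679, 998 to 1716 and 1040 to 1821 in the 3 contrasts. The correlation of changes ranged from 0.587 to 0.648 on leaving out each array, lowest without heterozygous replicate 3; the cause was not tested. Deviations of same-numbered arrays correlated weakly, at -0.0231 to 0.0695, against -0.0620 to 0.0341 for arrays of different numbers. Yet 7 of 9 arrays correlated best with an array of their own number, so a weak effect of replicate number cannot be excluded. With the replicate block, 8905, 3571, 5199 and 8619 probe sets were called. No F-test exists for the fit of 2 groups, and lists were not tested without moderation or with the 2-fold minimum. Signal over background is unknown for these arrays, so falls toward low values may be understated by an amount that was not measured.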

Other observations

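The gene groups in this paragraph were chosen after the data were seen, from the letters that begin gene symbols: 116 groups of at least 15 genes, adjusted over 348 tests with camera, of which 11 passed. Of these, 5 were in homozygous against wild type, 3 in heterozygous against wild type and 3 in homozygous against heterozygous blood. Not all of them are described here. Of 47 genes of the large subunit of the mitochondrial ribosome (Mrpl), 32 rose and 1 fell in homozygous blood (mean log2 0.31, adjusted p = 3.25e-08), and 20 rose and 2 fell in heterozygous blood (mean log2 0.16, adjusted p = 4.59e-06). Of 29 genes of the small subunit (Mrps), 17 rose and 2 fell in homozygous blood (mean log2 0.37, adjusted p = 1.47e-05), and 10 rose and 2 fell in heterozygous blood (mean log2 0.19, adjusted p = 0.0001). RNA polymerase subunit genes (Polr) rose in 12 of 25 and fell in 3 (adjusted p = 0.026), and genes of mitochondrial inner membrane import (Timm) rose in 7 of 15 and fell in 1 (adjusted p = 0.024). Ubiquitin-conjugating and related genes (Ube) fell in 13 of 38 and rose in 1 (adjusted p = 0.0268). None of these calls held with an estimated correlation, where the adjusted p in homozygous blood was 0.884 for each of Mrpl, Mrps, Polr and Timm and 0.91 for Ube. The Mrpl and Mrps means stay above 0 if the shifts of the reference genes, -0.04 in homozygous and 0.11 in heterozygous minus wild-type arrays, are taken off, and fall below 0 if those of the poly-A spike-ins are.

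Csf2rb changed by -0.68 and -0.72 in its 2 probe sets in heterozygous against wild-type blood, and was at 0.10 and 0.07 in homozygous minus wild-type blood, where it did not pass. Homozygous and heterozygous blood differed by 0.78 and 0.79.

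A knock-in allele can carry flanking chromosome of the strain it was made in, which might change probe signals of genes beside Cbfb. The test was written down before the counts were made. Of the 100 measured genes nearest to Cbfb in the order of the reference, 50 on each side, 21.0% differed between homozygous and wild-type blood against 25.7% of other genes (Fisher's exact test for an excess, p = 0.883). With 25 and 100 genes on each side the p was 0.924 and 0.671, so no excess was seen.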
